A study of Arabidopsis thaliana with 6 samples.

How the data were processed

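RNA from whole Arabidopsis thaliana seedlings of the Col-0 accession was sequenced in 6 libraries, 3 from seedlings kept in air and 3 from seedlings held under water for 1 h. Group and replicate number were taken from the sample titles and treatment labels. The design text names 3 biological replicates per group with air as the control, and says nothing more about how the replicates were grown apart, so p-values measure the spread between these samples.

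Total RNA was extracted with Trizol and libraries were made by a sequencing company, per the labels' protocols. The genome build is TAIR10, per the submitters' processing notes. The aligner, the counting program, their versions and the strand setting are not given in the sources used here.

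The deposited tables list 27655 genes, each with whole-number counts, RPKM, TPM and CPM for every library, per the file headers. The deposited CPM is a size-adjusted signal, since each library's values are its counts divided by 1 constant and do not sum to 1e6. The factors implied by those constants ran from 0.968 to 1.04, against 0.967 to 1.03 for the edgeR TMM factors computed here. The RPKM and TPM values made by the authors were not used in any test. A separate table deposited by the authors gives a log2 fold change, a p-value and a false discovery rate per gene for submerged against air; the test behind it is not given in the sources used here, and 4688 genes with no count in any library have no value in it.

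Among genes with 1 to 20 counts, 85.8% to 87.4% of counts were even in each library, against 49.1% to 51.1% among genes with more than 100 counts. Low counts were therefore read as read pairs counted as 2. The detection floor was set to 6 counts, or 3 read pairs, summed over a group. Intervals on ratios of low counts are exact binomial 95% intervals on halved counts and, like the floor, cover counting error alone.

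Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood F test with Benjamini-Hochberg adjustment over 19495 genes. Genes with an adjusted p under 0.05 were called. Fold changes are log2 of submerged over air, given with a standard error, and CPM values in the text were computed here from counts and TMM factors. Every adjusted p of a single gene is from this edgeR test unless another tool is named.

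A total of 16 gene lists were written from general knowledge of Arabidopsis before the data were examined, as were the main test, the rule for named genes and most alternatives. Lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 16 lists. Camera with an estimated correlation and fry were alternatives. No list passed camera with an estimated correlation, where 4 of 16 had an unadjusted p under 0.05 and the smallest adjusted p was 0.118.

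The rule named, among called genes with at least 5 CPM in the higher group and groups that did not overlap, the 8 with the largest rise and the 8 with the largest fall. It also took up to 3 called members per list with the largest changes, and always ADH1, PDC1, SUS4, PGB1, HRE1, HRE2, HRA1, LBD41, PCO1, PCO2, ACO1 and RAP2.12. Other list members are named where they went against their list, complete a small count or serve as further examples, such as ETR2, EBF2, RBOHD and IAA29. These were picked after their values were seen.

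Alternatives covered DESeq2 size factors, upper quartile scaling, library size alone, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom, removal of organelle genes, a replicate block and leaving out each library. A root-marker covariate, halved counts and the estimated correlation in fits with a block or a library left out were added after the data were seen. Genes of the TAIR10.1 annotation were used for names, products, exon counts and transcript lengths, and 27445 of the 27655 identifiers matched it. Positions on the genome are not given here, because that assembly is not the one named for the deposited values.

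The procedure was tested on simulated counts for the 19495 genes of this comparison, with 200 genes changed. Of 50 genes per size, 62% were recovered at 1.5-fold, 82% at 2-fold, 96% at 4-fold and 100% at 8-fold, none with the wrong sign. Of 19115 unchanged genes, 22 were called, which was 11.5% of the calls and above the nominal 5% set by the threshold. Since 200 genes were changed, against 10718 called in the data, neither this share nor the recovery rates carry over directly to the reported genes. Camera gave 2 of 100 unchanged lists a p under 0.05. The simulated genes were drawn independently, so this does not test the preset correlation for lists whose genes vary together. In the data the estimated correlation ran from -0.11 (mitochondrial dysfunction) to 0.81 (light harvesting) over the 16 lists.

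Pairs of libraries within a group differed by 4.38 to 8.81 times the variance expected if each deposited count were a separate read. This is a chi-square over degrees of freedom across genes. No library was therefore a copy of another. Between groups this ratio was 128 to 176.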

Results

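The series asked which genes respond to submergence in wild-type (Col-0) Arabidopsis seedlings. Seedlings grown for 14 days on agar plates spent 1 h under water, or stayed in air, before messenger RNA levels of whole seedlings were measured by RNA sequencing, with 3 libraries per group. In units of 1e6 counts, library totals were 25.9, 20.6 and 20.3 in air and 29.7, 22.2 and 20.04 in the submerged group. All values below are for n = 3 libraries per group, with SD for CPM (counts per 1e6 counts) and SE for log2 fold changes.

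Within 1 h of submergence, transcripts that were absent or near the detection floor in air rose to levels well above it. ERF105 (AT5G51190), an ethylene response factor family regulator, had 0 counts in the 3 air libraries and 52.7 ± 8.13 CPM under water, at least 594-fold higher against the floor. ERF019 (AT1G22810), of the same family, was at least 214-fold higher, and 3MMP (AT1G24140), a matrix metalloproteinase, at least 57.8-fold higher. The cysteine-rich transmembrane protein genes AT2G32200 and AT1G56060 were at least 205-fold and 107-fold higher. In the other direction, EXPA8 (AT2G40610), an expansin that loosens cell walls, fell from 46.9 ± 4.1 to 1.15 ± 0.560 CPM (log2 fold change -5.30 ± 0.19, adjusted p = 2.06e-10).

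The other genes among the 8 largest rises were AT2G38240, AT1G32910 and AT2G32140. AT2G38240, an oxygenase gene that the deposited table names ANS and that is also known as the jasmonate-induced oxygenase JOX4, rose by a log2 fold change of 8.39 ± 0.69, and all of its 8 air counts lay in air replicate 2, without which it was at least 322-fold higher against the floor. AT1G32910, an acyltransferase gene with 2 counts in air, had a ratio of 181 (95% counting interval 32.3 to 7223); both counts lay in air replicate 1, without which it was at least 36.3-fold higher against the floor. AT2G32140, annotated as a transmembrane receptor, had 4 counts in air and a ratio of 125 (34.3 to 1040), with log2 values from 6.2 to 7.29 when 1 library was left out. Among the largest falls after EXPA8 were the pectin lyase-like gene AT1G10640 (-5.30 ± 0.29, and -6.00 without submerged replicate 1), the basic helix-loop-helix growth regulator PRE1 (AT5G39860, -4.87 ± 0.24) and the auxin-responsive SAUR21 (AT5G18030, -4.00 ± 0.26). The LURP-one-like gene AT1G53875 (-3.91 ± 0.32), the pectin lyase-like gene AT1G60590 (-3.89 ± 0.29), the lectin gene AT1G52100 (-3.62 ± 0.10) and bHLH071 (AT5G46690, -3.50 ± 0.12) followed.

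Of 19495 genes tested, 10718 (55.0%) were called by edgeR's quasi-likelihood test, 5624 higher and 5094 lower under water. At least a 2-fold change was seen for 2980 of them, 1890 higher and 1090 lower. The asymmetry grew with size: 674 genes were at least 4-fold higher against 156 at least 4-fold lower, and 224 against 20 were changed at least 10-fold. The first principal component, which separated the groups, held 79.6% of the variance, and the libraries of the groups did not overlap for 12115 genes (62.1%, where chance gives 10%). The balance of directions depended on scaling. With upper quartile scaling, which shifted the median log2 fold change of all genes by -0.12, 4465 genes were higher and 6813 lower, so that 39.6% of calls were higher in place of 52.5%.

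**Figure D1:**
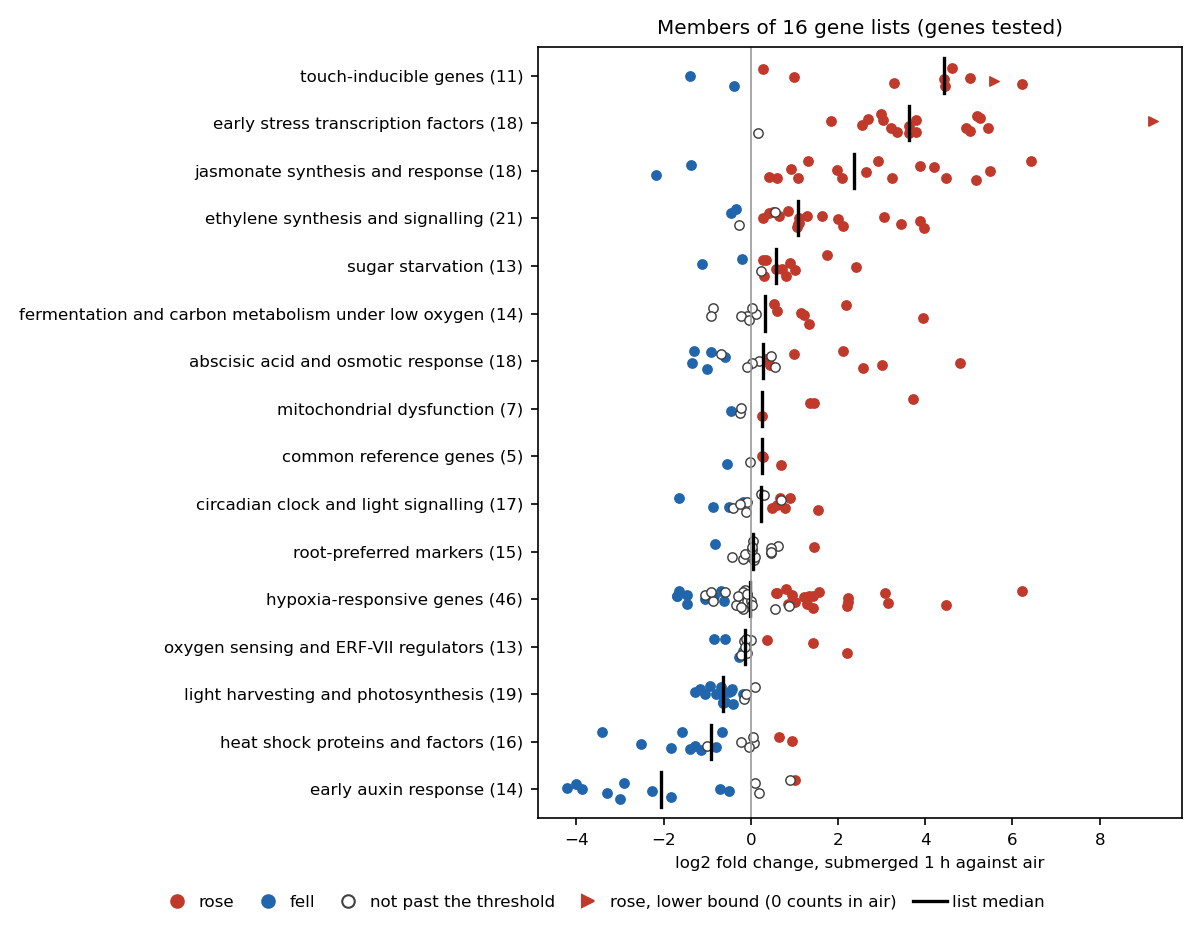
Each point is a tested gene of 1 of the 16 gene lists (number of genes in brackets), placed at its log2 fold change of submerged over air. Red points rose and blue points fell by edgeR's test, open points did not pass the threshold, triangles are lower bounds for genes with 0 counts in air, and black bars are list medians. The touch list (median 4.44) and the early stress transcription factors (3.63) lie to the right, and the early auxin list (-2.05) to the left.

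Calcium-sensor and cell wall genes known to respond to touch rose strongly. TCH3 (AT2G41100), a calmodulin-like protein, went from 46.8 ± 3.62 to 1521 ± 82.3 CPM (log2 fold change 5.02 ± 0.08, adjusted p = 1.43e-12). CML38 (AT1G76650), a calmodulin-like protein also listed as hypoxia-responsive, rose by 6.21 ± 0.12, and CML37 (AT5G42380), at 0 counts in air, was at least 47.8-fold higher. Of the 11 touch-inducible genes measured, 9 rose and 2 fell, with the same 9 and 2 when adjusted over the list alone. The 2 that fell, XTH25 (-1.39 ± 0.20) and XTH31 (-0.39 ± 0.15), encode xyloglucan-modifying enzymes, as does TCH4, which rose by 4.45 ± 0.12. The list median was 4.44 and camera gave an adjusted p of 0.00108, against an adjusted p = 0.118 with an estimated correlation. With upper quartile scaling 7 rose and 2 fell (median 4.32), and with the replicate block 8 rose and 1 fell.

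Early stress transcription factors moved together. Of 18 measured, 17 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 3.63. WRKY46 (AT2G46400), a defence-related regulator, rose by 5.44 ± 0.30, and ERF11 (AT1G28370), an ethylene response factor repressor, by 5.26 ± 0.20. DREB2A, a drought and heat regulator, stood at 0.16 ± 0.14 and did not pass the test. Camera gave the list an adjusted p of 7.65e-10, and adjusted p = 0.118 with an estimated correlation. CBF3, with 34 counts in air and 0 under water, was below the count filter and not tested.

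Jasmonate genes mostly rose, among them genes of synthesis and of turnover. CYP94C1 (AT2G27690), which oxidises jasmonoyl-isoleucine, went from 0.884 ± 0.512 to 78.3 ± 2.80 CPM (log2 fold change 6.41 ± 0.18, adjusted p = 3.35e-11). LOX4 (AT1G72520), a lipoxygenase of jasmonate synthesis, rose by 5.16 ± 0.15. JAZ8 (AT1G30135), a repressor of the pathway with 3 counts in air, had a ratio of 48.9 (95% counting interval 9.81 to 308; log2 values from 4.85 to 6.37 when 1 library was left out). Of 18 list members, 16 rose and 2 fell, unchanged when adjusted over the list alone; the 2 were LOX2 (-2.17 ± 0.08), a chloroplast lipoxygenase, and VSP2 (-1.36 ± 0.18), a vegetative storage protein gene. The list median was 2.36, with an adjusted p of 7.80e-06 by camera and adjusted p = 0.118 with an estimated correlation.

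Genes of ethylene synthesis and signalling mostly rose. ACS11 (AT4G08040) and ACS7 (AT4G26200), which make the ethylene precursor, rose by 3.88 ± 0.17 and 3.44 ± 0.37 on the log2 scale, and the response gene ERF1 (AT3G23240), with 4 counts in air, had a ratio of 17.62 (95% counting interval 4.55 to 151). The receptor gene ETR2 rose by 1.29 ± 0.08 and EBF2, an F-box gene that limits the response, by 1.64 ± 0.06. Of 21 genes, 17 rose and 2 fell (17 and 3 adjusted over the list alone). The 2 that fell were the signal transducers EIN2 (-0.34 ± 0.05) and EIL1 (-0.45 ± 0.06). Camera gave an adjusted p of 6.35e-05 for the list, and adjusted p = 0.118 with an estimated correlation. ACO1 (AT2G19590), an ethylene-forming oxidase, stood at 0.55 ± 0.26 with an adjusted p of 0.0906 by edgeR's test, while the authors' table calls it higher (false discovery rate 0.0417); without air replicate 2 it was 0.96, with an adjusted p of 0.00225.

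Classical low-oxygen markers were not called higher after 1 h. ADH1 (AT1G77120), alcohol dehydrogenase, had 12.9 ± 12.5 CPM in air and 7.04 ± 2.51 under water (log2 fold change -0.86 ± 0.51, adjusted p = 0.173). PDC1 (AT4G33070), pyruvate decarboxylase, stood at -0.08 ± 0.49 (adjusted p = 0.903) and SUS4 (AT3G43190), a sucrose synthase, at -0.91 ± 0.56 (adjusted p = 0.190). Other enzymes of low-oxygen metabolism did rise, among them GAD4 (AT2G02010), a glutamate decarboxylase (3.96 ± 0.56; 3.40 to 4.68 with 1 library left out), PPDK (AT4G15530), pyruvate orthophosphate dikinase (2.17 ± 0.12), and ALAAT1 (AT1G17290), alanine aminotransferase (1.33 ± 0.06). PGB1 (AT2G16060), a haemoglobin that scavenges nitric oxide, rose by 1.22 ± 0.33 (adjusted p = 0.00744), though not by DESeq2 (adjusted p = 0.0619). Of 14 genes of fermentation and carbon metabolism, 7 rose and 0 fell, also adjusted over the list alone; camera gave an adjusted p of 0.0633, and adjusted p = 0.285 with an estimated correlation.

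Among the group VII ethylene response factors that act in oxygen sensing, HRE1 (AT1G72360) rose by 2.21 ± 0.18 and RAP2.2 (AT3G14230) by 1.42 ± 0.06, while RAP2.12 (AT1G53910) rose by 0.38 ± 0.05. RAP2.3, of the same group, stood at -0.16 ± 0.06 (adjusted p = 0.0530, and 0.0478 adjusted over the list alone). HRA1 (AT3G10040), a repressor of RAP2.12 activity, fell by 0.84 on the log2 scale (SE 0.23). LBD41 (-0.12 ± 0.21), PCO1 (-0.01 ± 0.22) and PCO2 (-0.08 ± 0.42), which are common markers of the low-oxygen response, did not pass the test (adjusted p = 0.651, 0.980 and 0.889). HRE2, with 6 counts in air and 14 under water, was below the count filter. Of 13 list members, 3 rose and 4 fell (3 and 5 adjusted over the list alone). The median was -0.12 (-0.25 with upper quartile scaling), the mean 0.11, and camera gave a downward direction with an adjusted p of 0.685 (adjusted p = 0.746 with an estimated correlation).

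The wider list of hypoxia-responsive genes was split. Of 46 measured, 19 rose and 9 fell, also adjusted over the list alone. The largest rises after CML38 were EXL1 (AT1G35140, 4.48 ± 0.24), a phosphate-responsive family gene, and AT4G24110 (3.14 ± 0.30, and 3.81 without air replicate 2); RBOHD, an NADPH oxidase, rose by 1.43 ± 0.10. Those that fell included ATL23 (-1.70 ± 0.19), a RING finger gene. The median was -0.02 and the mean 0.47, and camera pointed upward with an adjusted p of 0.227 (adjusted p = 0.673 with an estimated correlation). The median changed sign with the setting: it was 0.58 with the filter of 5 CPM in 3 libraries (32 genes, 17 rose and 5 fell), 0.50 without air replicate 2 (21 rose and 8 fell) and -0.15 without air replicate 3 (18 rose and 11 fell).

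These low-oxygen values moved with the air replicate 2 library. Against the mean of the other air libraries, it was higher by 2.28 for ADH1, 2.116 for PDC1 and 2.50 for SUS4 on the log2 scale, and 35 of the 46 hypoxia-responsive genes were higher in it, with a median of 0.40. It was also higher in 14 of 15 root-preferred markers, by a median of 0.87, while air replicate 3 was lower in them, by a median of -1.24. Without air replicate 2, PDC1 was at 0.97 (adjusted p = 0.0325 by edgeR's test), PGB1 at 1.93, ADH1 at 0.31 (adjusted p = 0.382) and SUS4 at 0.43 (adjusted p = 0.279). The list of hypoxia-responsive genes then passed camera (adjusted p = 0.0303), as did the fermentation list (adjusted p = 0.0108), which also passed without submerged replicate 2. Neither passed without air replicate 2 under the other form of the test (adjusted p = 0.437 and adjusted p = 0.251 with an estimated correlation), nor did the fermentation list without submerged replicate 2 (adjusted p = 0.408 with an estimated correlation). Without air replicate 3, ADH1 was at -1.25 (adjusted p = 0.0331) and SUS4 at -1.31 (adjusted p = 0.0414).

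**Figure D2:**
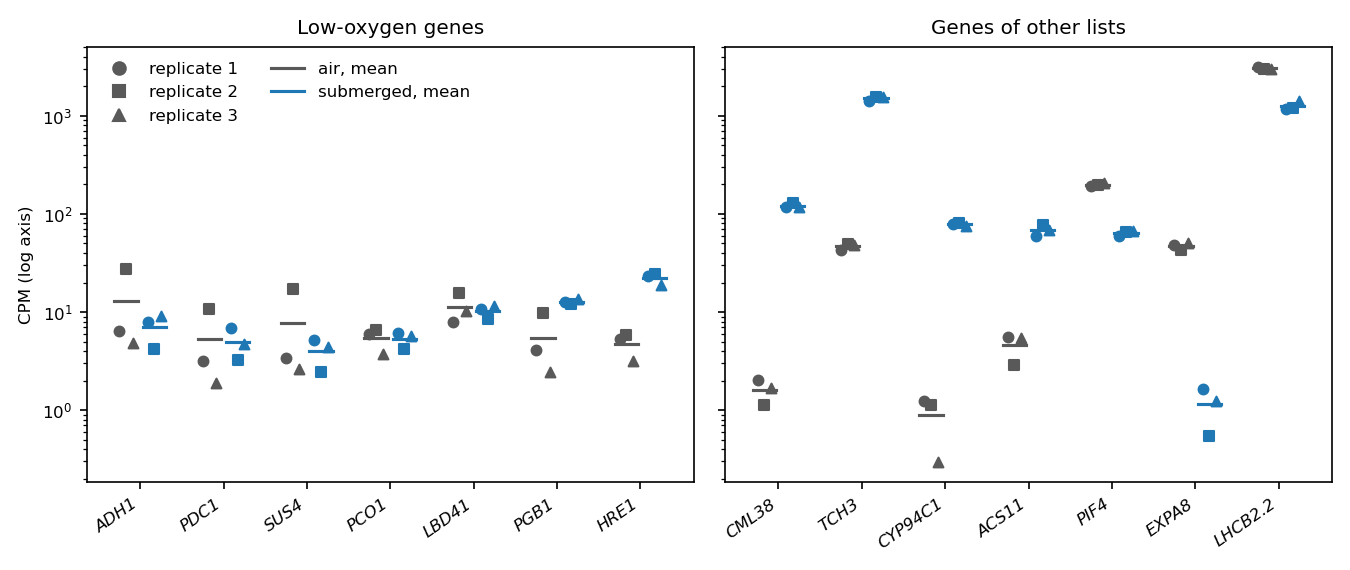
CPM of each library on a log axis for low-oxygen genes (left) and genes of other lists (right), with air in grey, submerged in blue, a marker shape per replicate number and a line at each group mean. Air replicate 2 is the highest library for ADH1 (27.3 CPM), PDC1 (10.8) and SUS4 (17.2), while TCH3, CYP94C1 and LHCB2.2 separate by group.

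**Figure D3:**
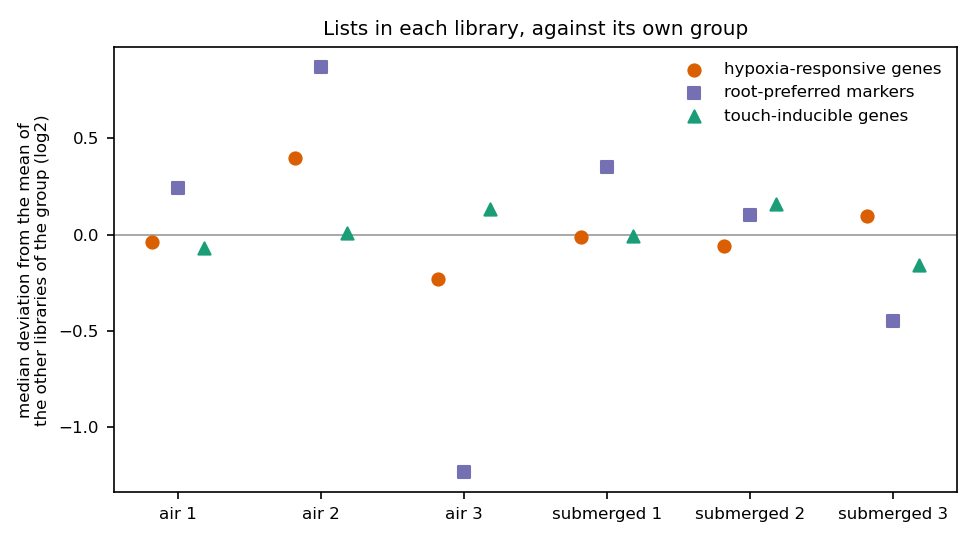
Median log2 difference of each library from the mean of the other libraries of its group, for the hypoxia-responsive genes (circles), the root-preferred markers (squares) and the touch-inducible genes (triangles). Air replicate 2 stands at 0.40 and 0.87 for the first and second of these lists and at 0.01 for the touch list, and air replicate 3 at -1.24 for the root markers.

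Most genes of the sugar starvation list rose. BCAT2 (AT1G10070), which degrades branched-chain amino acids, rose by 2.41 ± 0.21, and DIN10 (AT5G20250), a dark-inducible raffinose synthase family gene, went from 1328 ± 96.1 to 4442 ± 346 CPM (1.74 ± 0.07). Of 13 sugar starvation genes 10 rose and 2 fell, also adjusted over the list alone, the latter being TPS5 (AT4G17770, -1.11 ± 0.10), a trehalose phosphate synthase family gene, and BAM3 (-0.20 ± 0.07), a beta-amylase. Camera gave an adjusted p of 0.0363, and adjusted p = 0.568 with an estimated correlation. Submerged replicate 3 was higher than the other submerged libraries in 12 of the 13 genes, by a median of 0.25; without it the list median went from 0.59 to 0.35, 9 rose and 2 fell, and camera gave an adjusted p of 0.0477 (adjusted p = 0.490 with an estimated correlation).

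In the list of mitochondrial dysfunction, OM66 (AT3G50930), an outer membrane protein, rose by 3.72 ± 0.15, AOX1A (AT3G22370), alternative oxidase, by 1.45 ± 0.08, and NDB2 (AT4G05020), an alternative NADH dehydrogenase, by 1.35 ± 0.19. In all, 4 of 7 rose and 1, SOT12 (-0.46 ± 0.14), a sulfotransferase gene, fell, also adjusted over the list alone; the list did not pass camera (adjusted p = 0.341, and adjusted p = 0.568 with an estimated correlation).

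Abscisic acid and osmotic genes went both ways. CYP707A3 (AT5G45340), which inactivates abscisic acid, rose from 3.38 ± 0.158 to 94.1 ± 9.96 CPM (4.80 ± 0.10), and NCED3, which makes the hormone's precursor, fell by 1.34 on the log2 scale (SE 0.33). RD29A (AT5G52310) and COR47 (AT1G20440), known to be induced by cold and drought, rose from 10.5 ± 0.845 to 84.2 ± 14.6 CPM and by a log2 fold change of 2.57 ± 0.07. Of 18 genes 7 rose and 5 fell, also adjusted over the list alone, with an adjusted p of 0.479 by camera (adjusted p = 0.610 with an estimated correlation).

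Auxin-responsive growth genes fell. SAUR19 (AT5G18010), SAUR21 and SAUR22 (AT5G18050), small auxin-up RNAs that promote cell expansion, were lower by log2 fold changes of -4.21 ± 0.64 (-5.99 without submerged replicate 3), -4.00 ± 0.26 and -3.86 ± 0.39. These near-identical neighbours may share reads, which was not measured, so their separate values are uncertain. IAA29 (-2.26 ± 0.27), an auxin repressor gene, fell, and IAA2 (1.01 ± 0.06), of the same family, rose. Of 14 genes 1 rose and 10 fell, also adjusted over the list alone, with a median of -2.05. With the filter of 5 CPM in 3 libraries, which left 9 of the genes, 1 rose and 6 fell and the median was -0.73. Camera gave an adjusted p of 0.0119, and adjusted p = 0.546 with an estimated correlation.

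Light-harvesting genes were lower by a smaller amount. LHCB2.2 (AT2G05070) went from 3062 ± 101 to 1265 ± 126 CPM (-1.27 ± 0.07, adjusted p = 8.61e-09), LHCB2.1 (AT2G05100) stood at -1.17 ± 0.07 and LHCB1.1 (AT1G29920) at -1.06 ± 0.08. Copies of LHCB1 and LHCB2 may share reads, so the separate values are uncertain. All 13 chlorophyll-binding LHC genes fell, from -1.27 to -0.40, with a median of -0.69. The 4 Rubisco small subunit genes (RBCS), which may also share reads, ran from -0.17 to 0.09, and of these RBCS2B passed the test. Of 19 list members 0 rose and 16 fell, also adjusted over the list alone (18 fell with upper quartile scaling). Camera gave an adjusted p of 4.25e-06, and adjusted p = 0.546 with an estimated correlation.

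Heat shock genes were mostly lower. HSP15.7 (AT5G37670), HSP17.6C (AT1G53540) and HSP17.4 (AT3G46230), small heat shock proteins with related sequences, fell by 3.40, 2.51 and 1.83 on the log2 scale (SE 0.45, 0.35 and 0.34). The heat shock factor genes HSFB2A (0.94 ± 0.14) and HSFA7A (0.64 ± 0.11) rose. Of 16 genes 2 rose and 9 fell, also adjusted over the list alone; camera gave an adjusted p of 0.0384 (adjusted p = 0.568 with an estimated correlation), which was 0.0988 without air replicate 1 and 0.0691 without submerged replicate 1.

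Clock and light-signalling genes changed one by one. PIF4 (AT2G43010), a growth-promoting helix-loop-helix factor, fell from 200 ± 7.22 to 64.0 ± 3.34 CPM (-1.64 ± 0.06), while its relative PIF5 rose by 0.68 ± 0.05. The evening genes PRR5 (AT5G24470, 1.54 ± 0.09) and LUX (AT3G46640, 0.89 ± 0.06) rose and the morning genes CCA1 (-0.50 ± 0.12) and PRR9 (-0.87 ± 0.16) fell. Of 17 genes 6 rose and 4 fell, also adjusted over the list alone, with an adjusted p of 0.590 by camera (adjusted p = 0.673 with an estimated correlation).

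As a measure of tissue makeup, 15 root-preferred markers had a median log2 fold change of 0.04 (-0.08 with upper quartile scaling, 0.39 without air replicate 2 and -0.22 without air replicate 3). NRT2.1 (AT1G08090), a nitrate transporter with 20 counts in air, rose by 1.44 ± 0.48 (adjusted p = 0.0225) and PYK10 (AT3G09260), a root beta-glucosidase, fell by 0.82 (SE 0.11); adjusted over the list alone, 0 rose and 1 fell. NRT2.1 lost its call by DESeq2 (adjusted p = 0.0511), with no filter on low counts and without any of 5 single libraries. With halved counts or the filter of 5 CPM in 3 libraries, no marker was called higher. The mean of the markers was 2.42 ± 0.66 log2 CPM in air and 2.65 ± 0.20 under water (exact two-sided permutation p = 0.8, smallest possible 0.1), and camera gave the list an adjusted p of 0.847 (adjusted p = 0.943 with an estimated correlation). Of 5 common reference genes, ACT2 (AT3G18780) rose by 0.70 ± 0.05, UBQ10 (AT4G05320) by 0.27 ± 0.06 and EF1A, which may share reads with its copies, by 0.25 ± 0.06. GAPC2 (AT1G13440) fell by 0.55 (SE 0.07) and PP2AA3 stood at -0.01 ± 0.06; 3 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.479 by camera, and adjusted p = 0.746 with an estimated correlation).

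Organelle-encoded genes took 0.0170% ± 0.00211 of counts in air and 0.0206% ± 0.00205 under water (exact two-sided permutation p = 0.2, smallest possible 0.1). In the authors' deposited table, 10687 genes had a false discovery rate under 0.05, 5633 higher and 5054 lower. Of these, 10363 were also called by edgeR here, all in the same direction, while 355 were called here alone, 176 in the authors' table alone, and 148 of that table were not tested here.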

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

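The root-marker covariate, the halved counts and the estimated correlation in fits with a block or a library left out were chosen after seeing the data; every other alternative was chosen before. Over the alternatives, genes called ran from 9610 to 11278 against 10718, genes higher from 4465 to 5685, genes lower from 4456 to 6813, and genes with at least a 2-fold change from 2181 to 3073 against 2980, each within 1.5 times the reported count. With a replicate block, 10347 genes were called (5470 higher, 4877 lower, 2943 with at least a 2-fold change), 9 lists passed camera, and the fermentation list gained its call. No sign of pairing by replicate number was seen. Deviations of same-numbered libraries correlated across genes at -0.04, 0.04 and 0.04, and air replicate 2 correlated best with submerged replicate 1 (0.11). With 3 libraries per group, such weak correlations cannot exclude that same-numbered samples were handled together. Of the values of named genes outside leave-one-out, 728 kept direction and side of the threshold, 3 lost a call, 4 gained one and 7 changed sign, none of the 7 called on either side. The sign changes were PDC1 at 0.30, PCO1 at 0.0131 and PCO2 at 0.21 with limma voom, PDC1 at 0.19, PCO1 at 0.0044 and PCO2 at 0.10 with the replicate block, and PCO1 at 0.0034 with halved counts; the cause was not tested. Leaving out 1 library in turn gave ranges of -1.25 to 0.31 for ADH1, -0.47 to 0.97 for PDC1, -1.31 to 0.43 for SUS4, -0.33 to 0.19 for LBD41, -0.21 to 0.14 for PCO1 and -0.48 to 0.60 for PCO2, with the highest value of each without air replicate 2. With the root-marker covariate ADH1 (-0.92, adjusted p = 0.0490 by edgeR), SUS4 (-0.98, 0.0443) and ACO1 (0.42, 0.0359) passed the test. Of the 16 lists, 8 passed camera, 0 with an estimated correlation, 14 by directional fry and 15 by mixed fry, which do not compare a list with other genes; leaving out 1 library gave 7 to 10, and 0 with an estimated correlation, as with the block. The oxygen sensing list turned upward in directional fry (adjusted p = 0.0564). The root-preferred list turned downward with its own covariate (adjusted p = 0.535) and without air replicate 3 or submerged replicate 1, with adjusted p from 0.368 to 0.940 over the libraries left out; it was never called. Requiring at least a 2-fold change leaves 2976 genes shared with the authors' table, fewer by construction. Organelle shares differed by 0.00235 to 0.00473 percentage points over the libraries left out. An organelle share over protein-coding genes alone was not run, and alternatives meant for tables without counts do not apply. Depth limits the genes at or near 0 in air, whose folds are bounds or wide intervals.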

Other observations

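The families and the tests of the weighed explanations were chosen only after the results were seen, as was the test of introns without the families. The tests on other splits of the libraries, on intron number and on libraries of another duration were written down before their own results were seen, but after the genes with the largest changes and the list results were known. Among 22 families picked by name or product, 13 passed camera, 7 upward and 6 downward; 0 passed with an estimated correlation, where 6 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0612. Calmodulin-like genes moved in 1 direction: 23 of 29 rose and 0 fell (median log2 fold change 1.096, adjusted p = 1.44e-07, and adjusted p = 0.0612 with an estimated correlation), with CML40 at 5.72 and CML45 at 5.59. Of 50 WRKY factors 24 rose and 2 fell (adjusted p = 0.000224, and 0.149 with an estimated correlation), and of 70 ERF and DREB factors 43 rose and 12 fell (adjusted p = 7.66e-05, and 0.121 with an estimated correlation). TIR-domain genes, a class of immune receptors, rose in 43 of 94 cases and fell in 13, with none of the falls reaching 2-fold (adjusted p = 0.00275, and 0.149 with an estimated correlation).

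Among the families that passed camera downward, of 53 SAUR genes 33 fell and 6 rose (median -1.26, adjusted p = 0.000141, and 0.254 with an estimated correlation), AT3G09870 at 4.97 and AT4G34810 at 4.89 being the strongest exceptions. Alpha-expansins fell in 7 of 16 cases and rose in 1 (adjusted p = 0.0173, and 0.210 with an estimated correlation), aquaporins in 15 of 28 cases against 2 (adjusted p = 0.00837, and 0.300 with an estimated correlation), and cyclins in 9 of 28 against 2 (adjusted p = 0.00275, and 0.158 with an estimated correlation). Xyloglucan-modifying XTH genes passed upward, with 15 of 27 higher and 6 lower (adjusted p = 0.0159, and 0.149 with an estimated correlation), XTH18 at 5.70 among them. Of 7 gibberellin oxidases 2 rose and 2 fell (adjusted p = 0.709), GA2OX6, which removes the hormone, at 3.33 and GA20OX1, which makes it, at -4.00. All of these medians kept their sign with upper quartile scaling.

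Of the low-oxygen genes named in every case, 8 were tested and not called higher after 1 h: ADH1, PDC1, SUS4, HRA1, LBD41, PCO1, PCO2 and ACO1, while HRE1, PGB1 and RAP2.12 rose. With all libraries, the upper 95% limit of the log2 fold change reached 1, a 2-fold rise, for 1 of the 8, ACO1 (1.11). It was 0.98 for PDC1, 0.84 for PCO2, 0.31 for SUS4 and at most 0.48 for ADH1, HRA1, LBD41 and PCO1. A 2-fold rise thus remained possible for ACO1. These limits hold the spread between libraries as well as counting error, so they cannot show whether reads were too few. ACO1 had 456 counts in air and 708 under water. All of these limits, that of ACO1 included, rest on air replicate 2. Without that library the limit reached 1 for 4 of the 8, PDC1, SUS4, PCO2 and ACO1 (highest 1.71). A 2-fold rise hidden by air replicate 2 cannot be excluded for these. For the other genes the limit was at most 0.93, and HRA1 fell in both fits. The genes were divided by these same limits, so the division itself tests nothing. Whether oxygen had not yet fallen in the tissue cannot be told apart from a slow response, with 0 libraries of another duration.

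Air replicate 2 was high in low-oxygen genes. A mislabelled submerged library is argued against by its touch-inducible genes, whose median lay 0.00699 from the other air libraries on the log2 scale. More root tissue in that library may contribute, with root-preferred markers higher by a median of 0.87 than the mean of the other air libraries. That gap is in large part due to a low air replicate 3. It was also uneven across the markers, 14 of 15 being higher. NRT2.1 stood at -0.07, SCR at 0.12, PYK10 at 0.14 and PHT1;1 at 0.22, against 1.83 for PRP1 and 1.91 for IRT1. The median therefore does not stand for every marker, and a larger share of root would raise them all. Mean marker levels were 2.59, 2.98 and 1.70 log2 CPM in air replicates 1, 2 and 3, and 2.86 in submerged replicate 1. Whether root tissue is the whole cause cannot be told apart from an added difference: the median of the 46 hypoxia-responsive genes was 0.40, below that of the root markers, yet 5 of them, ADH1, PDC1 and SUS4 included, lay above the highest root marker, IRT1, at 1.91. No biological explanation was tested, since the labels give none for a single library.

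The light-harvesting genes were lower while Rubisco small subunit genes were nearly level. A smaller share of shoot tissue would lower both, and the RBCS median of -0.13 lay above the highest LHC gene, LHCB4.1 at -0.40. Over 4 scalings the LHC median was at most -0.69, the TMM value itself. The other scalings moved the median of all genes by -0.01 to -0.12, so they could not have raised it, and this comparison cannot decide. Counts taken up by strongly rising genes would lower LHC and RBCS genes alike, which leaves the gap between them (medians of -0.73 and -0.17 with library size alone). Sharing of reads between copies of LHCB1 and LHCB2 does not account for the lower LHC values, since 8 of 8 LHC genes outside them fell. A candidate explanation left is a regulated fall of these transcripts under water, a hypothesis found and examined on the same libraries.

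The 6 libraries can be split into 10 pairs of groups of 3, too few for a share under 0.05. For genes called by edgeR, 1 split, the real one, gave as many as 10718 genes, and the highest other split gave 0, with 327 genes at an unadjusted p under 0.05. For genes with at least a 2-fold change, 1 split gave as many as 2980, and the highest other split gave 0. Every other split mixed air and submerged libraries within its groups, which adds the difference between treatments to the spread within groups. Their 0 is therefore no measure of what chance would give.

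Strong early risers had fewer introns. The hypothesis, that genes answering fast are short of introns, was formed after the largest changes had been seen and written down before exon counts were compared, so it was tested on the libraries that prompted it. Of 669 genes called at least 4-fold higher with an annotated exon count, 38.9% had a single exon, against 15.8% of 8723 genes not called (odds ratio 3.38, Fisher's exact p = 1.14e-42, genes not being independent). Counting that treats short transcripts differently is argued against by a Mantel-Haenszel odds ratio of 3.40 within 5 classes of transcript length. Without the 22 families the share was 38.2% against 14.2% (odds ratio 3.73), and genes at least 4-fold lower had a single exon in 30.1% of cases (odds ratio 2.296), so the excess was not limited to risers.

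The largest falls bound the stability of some transcripts, if the scaling holds and decay was steady over the 60 min. At the upper 95% limit of its fold change, EXPA8 then had a half-life of at most 12.3 min, AT1G10640 of at most 12.9 min and PRE1 of at most 13.8 min. Of 768 genes that fell at least 2-fold with 5 CPM or more and groups that did not overlap, 9 had upper limits under 20 min and 50 under 30 min.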
